A study of Mus musculus with 6 samples.

How the data were processed

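CD45-negative lung cells of WT (C57BL/6J) and Ccr2KO mice were taken untreated (day 0) or 28 and 40 days after silica aspiration. Per the labels, lungs were digested with enzymes, erythrocytes and silica were removed on Percoll, and CD45-negative cells were isolated magnetically. Each of the 6 groups gave 1 RNA, pooled from 3 biological replicates, and 1 array. Pooled RNA gives no spread between animals. All 6 arrays lay on 1 slide, with WT untreated, Ccr2KO untreated and Ccr2KO day 28 in row 1 and the other 3 in row 2.

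Per the file headers, the authors scanned one-colour Cy3 arrays (design 028005) on an Agilent G2600D scanner and extracted background-subtracted, spatially and multiplicatively detrended intensity with Feature Extraction 11.0.1.1 and the protocol GE1_1100_Jul11. The deposited value table held the log2 of this processed intensity, without scaling between arrays, for 30574 probes, all of them above background on every array (largest difference from the scanner values 5e-09 log2), and the authors named R 2.15.1 for it. Its column medians were 9.82, 9.80 and 9.39 in WT and 9.52, 9.53 and 9.23 in Ccr2KO cells (untreated, day 28, day 40). A further 19 probes above background on every array were not in it. How probes were chosen for it is not given in the sources used here.

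The deposited scanner intensity of 62976 spots per array, 59305 of them not controls, was used. Control spots were removed, outlier spots (109 to 195 per array) were set to missing, repeated spots were averaged, and the log2 intensity was lowered by the 75th percentile of its array. No spot was saturated. The 55681 distinct probes were given symbols through their RefSeq names and the GRCm38.p6 gene set, with 27509 matching 1 symbol. Array annotation used the mm9 build and no positions are printed. Probes well above background on at least 2 of 6 arrays were kept, 35 with a missing value were left out, and a gene was read from its brightest probe, leaving 16440 genes, 4321 of them with several probes. The share of probes well above background was 64.4, 62 and 58.2% in WT and 63.5, 63.8 and 60.7% in Ccr2KO cells, and the 75th percentile of the signal 1179, 1159, 878, 969, 975 and 793 in the same order. Where a gene was well above background on no array of the lower side, its change is given as "at least". Each such array then counted at the gene's own signal or, if higher, at the lowest signal among probes well above background. A signal not above background could still lie higher than that, so such a fold is a nominal bound and not a strict limit. Correlations between genotypes on one day were 0.987, 0.991 and 0.985.

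Genes were tested with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with files read by the package data.table (1.17.8), at an adjusted p below 0.05 (Benjamini and Hochberg). An additive fit of day and genotype (2 residual degrees of freedom, prior 2.22) gave silica (days 28 and 40 against untreated), each day, day 40 against day 28, and Ccr2KO against WT. A fit of genotype by silica (prior 1.87) gave the difference of the silica responses and Ccr2KO against WT after silica. Gene lists for cell types, matrix, inflammation, stress and metabolism, 55 in number, were fixed before the data were examined, as were the comparisons, the genes of special interest, the naming rule and most alternatives. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. The 2 lists of sex-linked genes had fewer than 5 measured members and were not tested, which left 53. A list is given with its median, the members that passed over all genes, and the members that passed when adjusted over the list alone.

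Named genes passed the test, were above background on every array of the higher side and had one sign in every pair of arrays. Of these the 12 largest of each direction are given, or the 8 largest by value where fewer than 5 passed, with up to 4 members of each called list and 16 genes chosen in advance. Genes named for their clone are not given, and the values of some genes that the rule names are not reported here. On simulated data with 5 runs the silica comparison recovered 14.2% of 2-fold and 91.4% of 8-fold changes, day 40 against day 28 1.8 and 89%, Ccr2KO against WT 29.8 and 94.2%, and the difference of responses 0 and 0%. About 5% of unchanged genes had an unadjusted p below 0.05. Of 25 shifted lists simulated for silica camera recovered 25, and of 222 unshifted ones it called 1. The simulated genes varied independently of each other. These runs therefore cannot show how often camera calls an unshifted list whose genes vary together.

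Alternatives tried were normexp background correction with an offset of 50, quantile normalization, the authors' table, no filter, probes above background on all 6 arrays, the mean of a gene's probes, an intensity trend with a robust prior, the slide row as a block, leaving out each array, 2 other models of time, and the 2 other list tests. Chosen after seeing the data were the mean of the pan-leukocyte list as a covariate and the list test for day 40 against day 28. Probes without a symbol (28172) entered no comparison of genes.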

Results

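Ccr2, the chemokine receptor gene targeted in the knockout, read 0.09, 1.38 and −1.70 in WT cells (untreated, day 28 and day 40 after silica aspiration) and −5.07, −1.51 and −3.64 in Ccr2KO cells, as log2 signal relative to the 75th percentile of each array. The Ccr2KO minus WT difference was −3.33 ± 0.66 (log2 difference ± SE, limma adjusted p = 0.415 over 16440 genes, n = 3 arrays per genotype) and was negative on all 3 days, from −5.16 to −1.94. Where the Ccr2 probe lies relative to the deleted sequence is not given in the sources used here. Ptprc, which encodes the leukocyte antigen CD45 used to deplete these lung preparations, read 1.54, 2.62 and 0.29 in WT and 0.45, 2.14 and −0.61 in Ccr2KO cells. The 12 pan-leukocyte genes averaged 2.80, 4.04 and 1.78 in WT and 1.82, 3.60 and 1.31 in Ccr2KO cells. These 2 readings were highest at day 28 and lower in Ccr2KO than in WT on each day, unlike neutrophil genes, which averaged higher in Ccr2KO on each day. Each genotype and day had 1 array of RNA pooled from 3 biological replicates, so there were no replicates. The p-values of the gene tests therefore measure what a model of day and genotype left unexplained, on 2 residual degrees of freedom unless another number is given.

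After silica (mean of days 28 and 40 minus untreated, both genotypes), the largest increases were in Grem1, a BMP antagonist (8.19 ± 0.48, adjusted p = 0.00765), and the acute phase genes Saa3 (7.10 ± 0.54, adjusted p = 0.0086) and Saa1 (6.07 ± 0.21, adjusted p = 0.00653). Mmp10, a matrix metalloproteinase, rose at least 68.4-fold and Glycam1, a mucin-like ligand of L-selectin, at least 62.8-fold, both from untreated arrays on which they were not above background (adjusted p = 0.00658 and 0.00975). Further increases were in Chl1, a neural adhesion molecule (6.01 ± 0.40), Wnt10a, a Wnt ligand (5.83 ± 0.20, above background on 1 of 2 untreated arrays), and Dmbt1, a mucosal scavenger receptor (5.51 ± 0.34). From untreated arrays without signal above background, Tff1, a trefoil peptide of mucus, rose at least 53.5-fold, the mast cell protease gene Mcpt1 at least 46.9-fold, the Wnt antagonist gene Frzb at least 44.1-fold and Serpinb5, a serpin, at least 39.5-fold. The largest decreases were in Slc7a10, a neutral amino acid transporter (−3.78 ± 0.59, adjusted p = 0.0242), Cst8, a cystatin (−3.70 ± 0.23), and Slc5a12, a monocarboxylate transporter (−3.50 ± 0.40). The platelet genes Ppbp (−3.40 ± 0.22), Gp9 (−3.26 ± 0.23) and Gp5 (−2.96 ± 0.52), Acoxl, an acyl-CoA oxidase relative (−3.18 ± 0.25), and Fbxw22 (−3.06 ± 0.16) also fell. Ankrd63 fell at least 12.7-fold, Tcl1b5 at least 11.7-fold, Hsd3b2, a steroid dehydrogenase gene, at least 10.8-fold and the olfactory receptor gene Olfr750 at least 8.62-fold, all to signals not well above background (a second Hsd3b2 probe gave −0.98). Adjusted p of the 24 genes lay between 0.00653 and 0.0309, with the same sign in all 4 comparisons of a silica array with its own untreated array (n = 4 silica and 2 untreated arrays).

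Among genes chosen before the data were examined, the fibrillar collagen genes Col1a1 (1.58 ± 0.16, adjusted p = 0.0114) and Col3a1 (1.72 ± 0.16, adjusted p = 0.0105), fibronectin Fn1 (1.73 ± 0.11), the smooth muscle actin gene Acta2 (0.97 ± 0.18, adjusted p = 0.0331), osteopontin Spp1 (4.06 ± 0.18) and the metalloproteinase inhibitor Timp1 (3.35 ± 0.14) rose. The CCR2 ligand genes Ccl2 (2.30 ± 0.23), Ccl7 (2.72 ± 0.34) and Ccl12 (1.60 ± 0.21) also rose, as did the related chemokine Ccl8 (3.58 ± 0.61, adjusted p = 0.0289). Ager, a marker of type 1 alveolar (AT1) cells, fell by 1.43 ± 0.25 (adjusted p = 0.0306). Ccr2 (1.13 ± 0.70, adjusted p = 0.307), the surfactant gene Sftpc (0.11 ± 0.10, adjusted p = 0.474), the club cell gene Scgb1a1 (0.00 ± 0.09, adjusted p = 0.975), the endothelial gene Pecam1 (0.04 ± 0.17, adjusted p = 0.871) and Ptprc (0.11 ± 0.16, adjusted p = 0.642) did not pass. In all 3248 of 16440 genes changed, 1722 up and 1526 down, of which 964 and 563 by at least 2-fold. An unadjusted p below 0.05 was reached by 6161 genes. The slide row of the arrays as a block, or leaving out either day 28 array, gave 0 called genes, with 1 residual degree of freedom in each of these fits. The 4 silica arrays minus their own untreated array differed by at least 2-fold in one direction for 827 genes (555 up, 272 down).

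**Figure D1:**
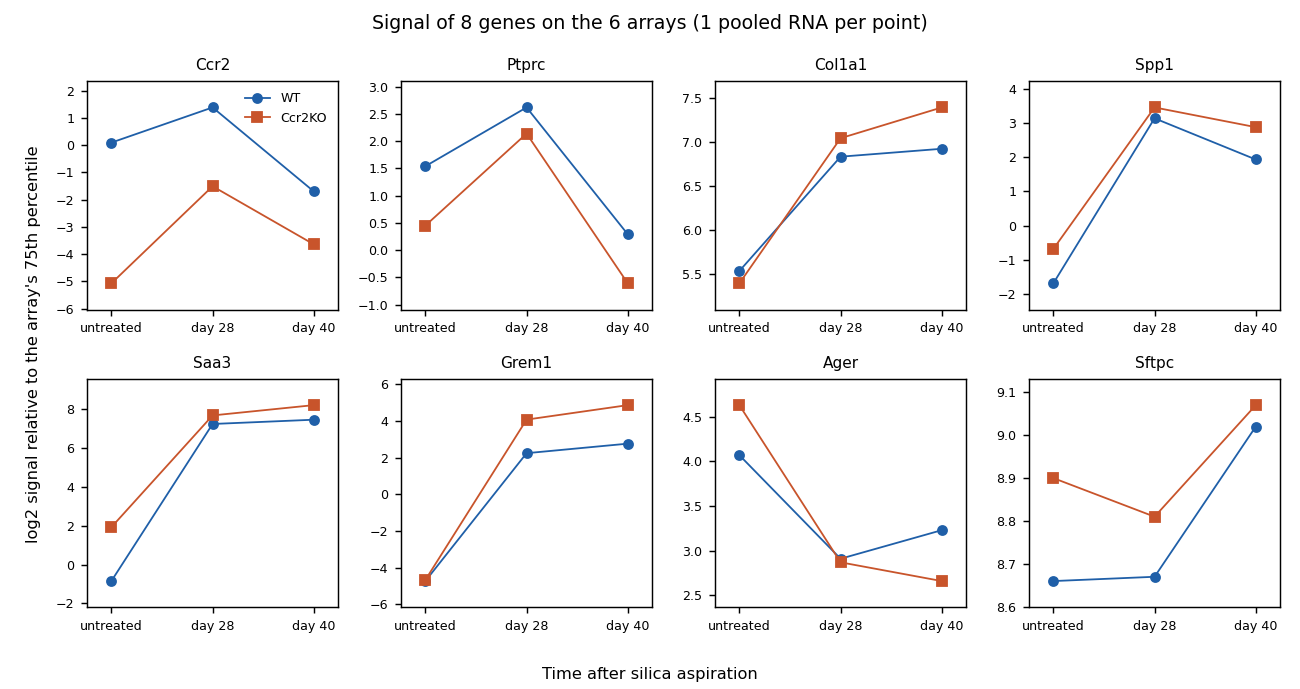
Log2 signal relative to the 75th percentile of the array (vertical axis) for 8 genes in untreated, day 28 and day 40 cells (horizontal axis), WT as circles and Ccr2KO as squares, 1 pooled RNA per point. Col1a1 went from 5.53 to 6.93 in WT and from 5.39 to 7.39 in Ccr2KO cells between untreated and day 40, while Ptprc peaked at day 28 in both (2.62 and 2.14).

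Matrix gene lists rose together after silica. Of 18 fibrillar and network collagens, 15 rose and 3 did not pass (median 1.59, camera adjusted p = 6.8e-10), and 18 rose when adjusted over the list alone (adjusted p = 0.428 with an estimated correlation). Among them were Col15a1 (2.73 ± 0.27), Col5a2 (2.38 ± 0.18), Col10a1 (at least 30.5-fold) and Col11a1 (at least 36.4-fold). Of 14 activated fibroblast genes, 11 rose and 3 did not pass (median 1.33, camera adjusted p = 3.1e-07; adjusted p = 0.378 with an estimated correlation), 12 when adjusted over the list alone. Lrrc15 (at least 37.2-fold), Ltbp2, a TGF-beta binding protein gene (3.14 ± 0.09), and tenascin Tnc (3.06 ± 0.24) rose. Matrix glycoproteins and crosslinking genes gave 16 of 25 up and 9 not passing (median 0.94, camera adjusted p = 1.71e-06), and 18 up and 1 down when adjusted over the list alone. Thbs2 (4.49 ± 0.25), the lysyl oxidase gene Loxl2 (2.29 ± 0.29, a second probe 1.34) and Fmod (2.01 ± 0.09) rose. Among 19 matrix proteases and inhibitors, 11 rose and 8 did not pass, also 11 when adjusted over the list alone (median 1.33, camera adjusted p = 7.94e-06). Mmp13 (4.99 ± 0.44) and Mmp8 (3.04 ± 0.22) rose. Of 15 TGF-beta targets, 7 rose and 8 did not pass (median 0.60, camera adjusted p = 0.00101), 8 when adjusted over the list alone. Inhba (3.12 ± 0.18) and Pmepa1 (0.95 ± 0.10) rose. The last 3 lists each had adjusted p = 0.378 with an estimated correlation. With the slide row as a block the collagen and activated fibroblast medians were 1.62 and 1.67, and within slide row 1 (Ccr2KO day 28 minus untreated) 1.57 and 1.49.

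Proliferation and inflammation lists also rose. Of 29 cell cycle genes, 25 rose and 4 did not pass (median 1.83, camera adjusted p = 1.53e-14), and 27 rose when adjusted over the list alone. The mitotic kinase Aurkb (at least 6.9-fold), topoisomerase Top2a (2.55 ± 0.13), Cdk1 (2.52 ± 0.17) and Birc5 (2.34 ± 0.12) rose. Acute phase and innate defence genes gave 17 of 19 up and 2 not passing, also 17 when adjusted over the list alone (median 1.68, camera adjusted p = 6.8e-10). The orosomucoids Orm2 (4.87 ± 0.15) and Orm1 (4.81 ± 0.34) rose. Of 26 inflammatory chemokines and cytokines, 11 rose and 15 did not pass (median 1.24, camera adjusted p = 6.15e-06), 14 up and 1 down when adjusted over the list alone. The neutrophil growth factor Csf3 (4.90 ± 0.94, adjusted p = 0.0364), the neutrophil chemokine Cxcl5 (4.75 ± 0.17), the T cell chemokine Cxcl9 (3.85 ± 0.58) and the B cell chemokine Cxcl13 (3.79 ± 0.24) rose. CCR2 ligands and monocyte chemokines gave 6 of 10 up and 4 not passing (median 1.30, camera adjusted p = 0.00132), 8 up and 1 down when adjusted over the list alone. Of 14 genes of lymphoid organ stroma, 9 rose, 1 (Chst4, a sulfotransferase gene) fell and 4 did not pass (median 1.09, camera adjusted p = 0.000319), and 10 rose and 1 fell when adjusted over the list alone. Tnfsf11, the RANK ligand gene (3.24 ± 0.43), and lymphotoxin Lta (1.92 ± 0.11) rose. Each of these 5 lists had adjusted p = 0.378 with an estimated correlation. Complement gave 7 of 17 up and 10 not passing (median 0.87, camera adjusted p = 0.00298; adjusted p = 0.579 with an estimated correlation), 10 up and 1 down when adjusted over the list alone. Cfi (2.42 ± 0.17), Cfb (1.95 ± 0.19) and C1qc (1.52 ± 0.28) rose, and Cfd gave 2.99 ± 0.91 (adjusted p = 0.0926).

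The interferon-gamma response list was not called after silica (median 0.09, adjusted p = 0.229). Type I interferon response genes gave 7 of 22 up and 15 not passing, also 7 when adjusted over the list alone (median 0.32, camera adjusted p = 0.00387; adjusted p = 0.653 with an estimated correlation). The nucleic acid sensor Zbp1 (1.91 ± 0.21), Rsad2 (1.66 ± 0.21), Oas3 (1.30 ± 0.21) and Irf7 (1.20 ± 0.18) rose. Of 13 MHC class I presentation genes only the immunoproteasome gene Psmb8 rose (0.54 ± 0.09) and 12 did not pass, 1 when adjusted over the list alone (median 0.25, camera adjusted p = 0.0137; adjusted p = 0.497 with an estimated correlation). Tap1 at 0.45 ± 0.11, H2-K1 at 0.37 ± 0.11 and B2m at 0.35 ± 0.11 did not pass. The MHC class II presentation list was called up with none of its 10 genes passing, and 0 when adjusted over the list alone (median 0.36, camera adjusted p = 0.00677; adjusted p = 0.469 with an estimated correlation). Ciita at 0.76 ± 0.25, H2-DMb2 at 0.61 ± 0.17, Cd74 at 0.45 ± 0.14 and H2-Aa at 0.44 ± 0.10 did not pass. Hypoxia and glycolysis genes gave 7 of 17 up, 2 down (Vegfa −1.07 ± 0.16, Car9 −0.44 ± 0.09) and 8 not passing, 7 up and 3 down when adjusted over the list alone (median 0.27, camera adjusted p = 0.0407; adjusted p = 0.598 with an estimated correlation). Egln3 (2.55 ± 0.11), Ankrd37 (2.22 ± 0.14), Ndrg1 (1.34 ± 0.14) and the glucose transporter Slc2a1 (0.88 ± 0.11) rose. The hypoxia call ended when any array except Ccr2KO untreated or Ccr2KO day 28 was left out, and with the slide row as a block (0.04, adjusted p = 0.18). The type I interferon call ended without WT untreated (0.16, adjusted p = 0.129) and the MHC class I call without Ccr2KO untreated (0.28, adjusted p = 0.055). Quantile normalization also ended the MHC class I call (0.16, adjusted p = 0.0794), and normexp background correction the hypoxia call (0.24, adjusted p = 0.0505).

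Alveolar epithelial lists fell. Of 11 AT1 genes, 8 fell and 3 did not pass (median −1.33, camera adjusted p = 0.000267; adjusted p = 0.579 with an estimated correlation), 9 down and 1 up when adjusted over the list alone. Hopx (−2.14 ± 0.25), Akap5 (−2.02 ± 0.18) and Emp2 (−1.37 ± 0.24) fell. Type 2 alveolar (AT2) genes gave 9 of 14 down and 5 not passing (median −0.74, camera adjusted p = 0.000387; adjusted p = 0.566 with an estimated correlation), 10 when adjusted over the list alone. The transcription factor Etv5 (−1.18 ± 0.09), Sfta2 (−1.15 ± 0.10), the phosphate transporter Slc34a2 (−0.94 ± 0.13) and Cxcl15 (−0.90 ± 0.12) fell. Of 15 surfactant lipid genes, 7 fell, 1 rose (lipoprotein lipase Lpl, 0.74 ± 0.15) and 7 did not pass (median −0.56, camera adjusted p = 0.00387; adjusted p = 0.378 with an estimated correlation), 8 down and 1 up when adjusted over the list alone. Lpcat1 (−1.08 ± 0.17), Plpp3 (−1.06 ± 0.14) and Pla2g1b (−1.05 ± 0.11) fell. Xenobiotic metabolism gave 7 of 20 down, 2 up and 11 not passing (median −0.56, camera adjusted p = 0.00863; adjusted p = 0.531 with an estimated correlation), 9 down and 3 up when adjusted over the list alone. Cyp4b1 (−2.07 ± 0.15), Fmo1 (−1.82 ± 0.11) and Fmo2 (−1.53 ± 0.28) fell, Cyp1b1 rose (3.23 ± 0.14), and Cyp1a1 gave −2.37 ± 0.76 (adjusted p = 0.102). Of 12 mucous cell genes, 7 rose and 5 did not pass (median 0.96, camera adjusted p = 0.000137; adjusted p = 0.378 with an estimated correlation), 8 when adjusted over the list alone. The intelectin Itln1 (4.43 ± 0.11), lactoferrin Ltf (2.29 ± 0.14) and Agr2 (1.68 ± 0.11) rose, and Clca1 gave 2.85 ± 1.15 (adjusted p = 0.157). Ciliated (median −0.12, adjusted p = 0.232) and club cell genes (−0.02, adjusted p = 0.965) were not called. Of 7 basal cell genes, 4 rose and 3 did not pass, 5 when adjusted over the list alone (median 1.57, camera adjusted p = 0.0357; adjusted p = 0.579 with an estimated correlation). The keratins Krt5 (3.21 ± 0.58), Krt14 (3.16 ± 0.41) and Krt17 (2.97 ± 0.40) and Ngfr (1.57 ± 0.15) rose. The basal cell call ended without either early Ccr2KO array (untreated, 1.5, adjusted p = 0.105, and day 28, 1.65, adjusted p = 0.0967).

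Among other structural lists, 6 of 8 mesothelial genes fell and 2 did not pass (median −0.87, camera adjusted p = 7.78e-05; adjusted p = 0.378 with an estimated correlation), 7 when adjusted over the list alone. Gpm6a (−1.45 ± 0.11), Upk3b (−1.36 ± 0.18), Lrrn4 (−1.25 ± 0.11) and Rspo1 (−0.90 ± 0.09) fell. Of 10 alveolar capillary endothelium genes, 3 fell and 7 did not pass, also 3 when adjusted over the list alone (median −0.57, camera adjusted p = 0.0326; adjusted p = 0.398 with an estimated correlation). Fibin (−1.98 ± 0.30), the endothelin receptor Ednrb (−1.96 ± 0.23) and Hilpda (−1.13 ± 0.16) fell, and Kitl gave −0.92 ± 0.26 (adjusted p = 0.0814). Lymphatic endothelium gave 4 of 8 up and 4 not passing (median 0.79, camera adjusted p = 0.00698; adjusted p = 0.378 with an estimated correlation), 6 up and 1 down when adjusted over the list alone. Nts (2.21 ± 0.39), the lymphatic regulator Prox1 (1.42 ± 0.19), Reln (0.96 ± 0.13) and Mmrn1 (0.88 ± 0.11) rose. Cardiac and skeletal muscle genes gave 6 of 12 down, 1 up (Acta1 1.17 ± 0.18) and 5 not passing (median −0.68, camera adjusted p = 0.0154; adjusted p = 0.378 with an estimated correlation), 7 down and 1 up when adjusted over the list alone. Sln (−2.17 ± 0.22), Actc1 (−1.47 ± 0.33), the atrial myosin Myh6 (−1.35 ± 0.11) and Myl7 (−1.33 ± 0.18) fell. Of 16 circadian clock genes, 3 fell and 13 did not pass, also 3 when adjusted over the list alone (median −0.41, camera adjusted p = 0.0208; adjusted p = 0.378 with an estimated correlation). Hlf (−0.96 ± 0.16) and Cry2 (−0.93 ± 0.11) fell, and Ciart at −0.82 ± 0.25 and Nr1d1 at −0.62 ± 0.16 did not pass. The alveolar capillary call ended with the slide row as a block (−0.56, adjusted p = 0.212), without WT day 28 (−0.54, adjusted p = 0.0555) and without Ccr2KO day 40 (−0.57, adjusted p = 0.0569), and the circadian call without Ccr2KO untreated (−0.29, adjusted p = 0.0532). The authors' table ended the cardiac muscle (−0.86, adjusted p = 0.058) and alveolar capillary calls (−0.76, adjusted p = 0.0885).

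Blood cell lists moved in both directions. Platelet and megakaryocyte genes gave 9 of 10 down and 1 not passing, also 9 when adjusted over the list alone (median −1.88, camera adjusted p = 1.47e-05; adjusted p = 0.378 with an estimated correlation). Treml1 (−2.79 ± 0.17) and Gp6, a collagen receptor gene (at least 5.94-fold lower) fell. Of 9 erythroid genes, 6 fell and 3 did not pass (median −2.30, camera adjusted p = 0.000387; adjusted p = 0.579 with an estimated correlation), 7 when adjusted over the list alone. The globins Hbb-bt (−2.46 ± 0.27), Hba-a1 (−2.40 ± 0.30) and Hbb-b2 (−2.38 ± 0.28) and the haem synthesis gene Alas2 (−2.41 ± 0.30) fell. Neutrophil genes gave 8 of 11 up and 3 not passing (median 1.43, camera adjusted p = 1.64e-05; adjusted p = 0.378 with an estimated correlation), 9 when adjusted over the list alone. The granule genes Mpo (3.30 ± 0.17), Ngp (3.25 ± 0.12) and Camp (2.57 ± 0.34) rose. Of 7 mast cell and basophil genes, 5 rose, 1 fell (Gata2 −1.01 ± 0.15) and 1 did not pass (Mcpt4 2.96 ± 0.84), and 6 rose and 1 fell when adjusted over the list alone (median 1.66, camera adjusted p = 0.0154; adjusted p = 0.598 with an estimated correlation). Cma1 (3.34 ± 0.61), Cpa3 (2.87 ± 0.38) and Fcer1a (1.66 ± 0.31) rose. Macrophage and monocyte genes gave 7 of 16 up and 9 not passing, also 7 when adjusted over the list alone (median 0.75, camera adjusted p = 0.0198; adjusted p = 0.656 with an estimated correlation). Trem2 (2.08 ± 0.43), Gpnmb (1.90 ± 0.25), Ms4a7 (1.66 ± 0.31) and Cd14 (1.54 ± 0.15) rose. T and NK cell genes gave 4 of 13 up and 9 not passing, also 4 when adjusted over the list alone (median 0.30, camera adjusted p = 0.0198; adjusted p = 0.654 with an estimated correlation). Cd3g (1.31 ± 0.11), Il7r (0.99 ± 0.12), Cd3e (0.90 ± 0.09) and Lck (0.72 ± 0.14) rose. The T and NK mean exceeded untreated at day 28 only (WT 0.14, 1.01, −0.53, Ccr2KO −0.45, 1.02, −0.67 at days 0, 28, 40). The same held for MHC class II and for WT macrophages.

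Of 12 pan-leukocyte genes, 3 rose after silica (Cd53 0.79 ± 0.12, Lcp1 0.70 ± 0.12, Cd52 0.68 ± 0.14) and 9 did not pass, among them Rac2 at 0.57 ± 0.14, and 4 rose when adjusted over the list alone (median 0.42, camera adjusted p = 0.0224; adjusted p = 0.697 with an estimated correlation). The list medians of single silica arrays against their untreated array ran from −1.15 to 1.73. Of 21 dissociation and immediate early genes, 2 fell (Egr1 −0.78 ± 0.15, Btg2 −0.74 ± 0.14) and 19 did not pass, and 0 when adjusted over the list alone (median −0.22, camera adjusted p = 0.0163; adjusted p = 0.72 with an estimated correlation). Atf3 at −0.86 ± 0.25 and Fosb at −0.83 ± 0.27 did not pass. Without Ccr2KO untreated the calls ended for pan-leukocyte (−0.02, adjusted p = 0.561), macrophage (−0.12, adjusted p = 0.793), T and NK cell (0.30, adjusted p = 0.442) and immediate early genes (−0.09, adjusted p = 0.561). They also ended without Ccr2KO day 28 for T and NK cell (0.26, adjusted p = 0.0738), pan-leukocyte (0.36, adjusted p = 0.0769) and immediate early genes (−0.17, adjusted p = 0.0594), and without Ccr2KO day 40 for pan-leukocyte (0.24, adjusted p = 0.0565), macrophage (0.46, adjusted p = 0.0894) and immediate early genes (−0.23, adjusted p = 0.0574). Without a filter on dim probes the pan-leukocyte (adjusted p = 0.0579), macrophage (0.0579), T and NK cell (0.053), basal cell (0.0525) and hypoxia calls (0.114) ended. With silica as 1 group against day 0 the pan-leukocyte (adjusted p = 0.462), T and NK cell (0.302), immediate early (0.174) and MHC class II calls (0.0715) ended. Of 53 lists, camera called 23 up and 11 down, fry called 23 (21 of them called by camera), and 0 were called with an estimated correlation. Fry did not call AT1 (adjusted p = 0.0795), basal (0.0934), erythroid (0.0834), mast (0.118), macrophage (0.264) and T and NK cells (0.0954), or complement (0.0834). It also left out xenobiotic metabolism (0.08), type I interferon (0.179), MHC class II (0.0601), hypoxia (0.0707), pan-leukocyte (0.216) and immediate early genes (0.291). Of the 19 lists not called, endothelial (median −0.22, adjusted p = 0.0726), plasma cell (0.38, adjusted p = 0.0789) and adipocyte genes (0.76, adjusted p = 0.0789) came nearest. The median, mean and test direction differed in sign for 6 lists, none of them called: sterol synthesis (−0.07), transitional epithelium (−0.27), alveolar niche growth factors (−0.03), club cells (−0.02), NRF2 (0.09) and heat shock (0.12).

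**Figure D2:**
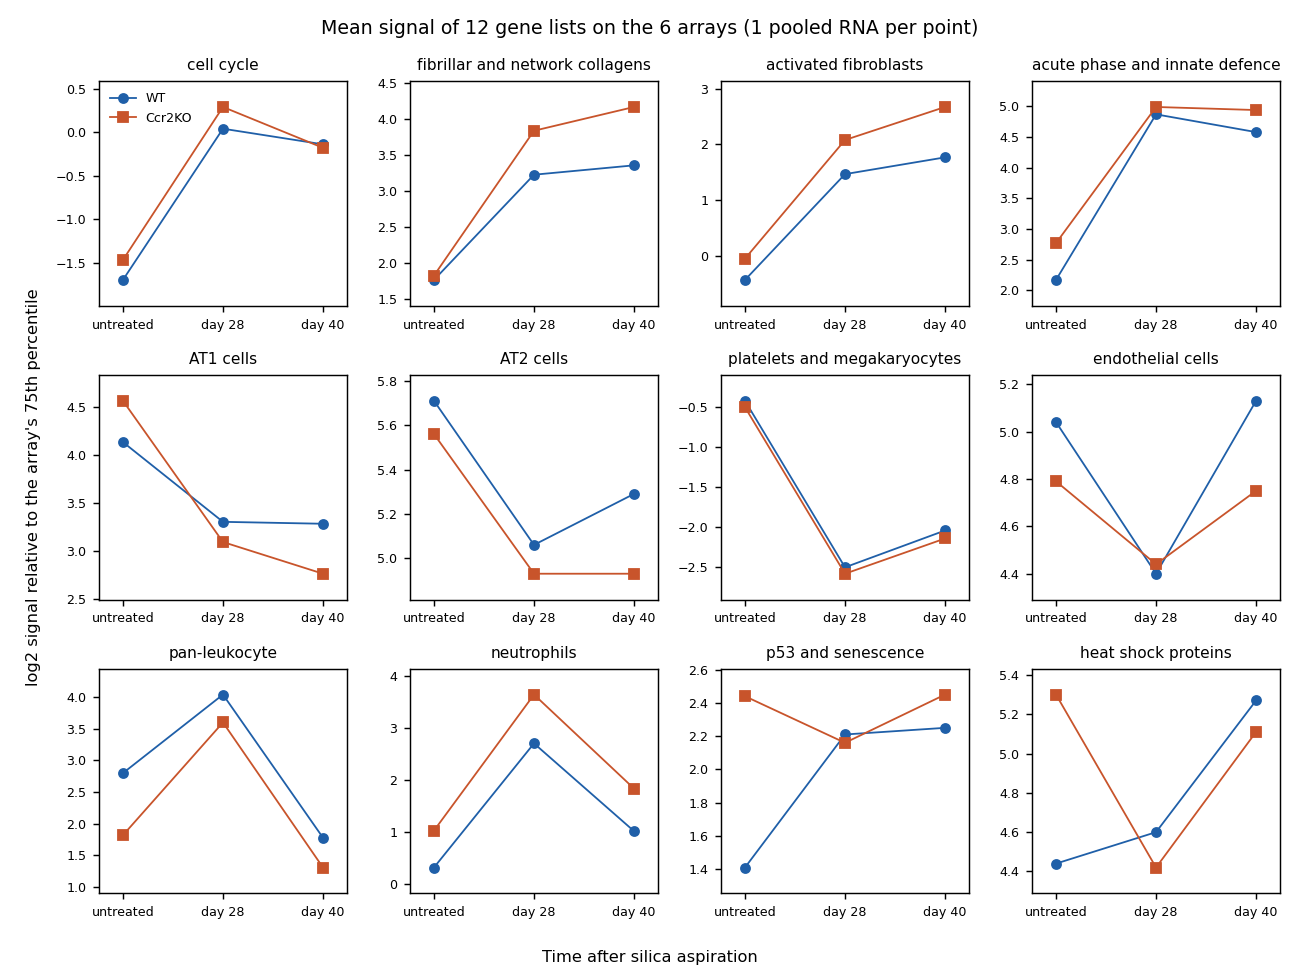
Mean log2 signal relative to the 75th percentile of the array (vertical axis) of 12 gene lists in untreated, day 28 and day 40 cells (horizontal axis), WT as circles and Ccr2KO as squares, 1 pooled RNA per point. The collagen mean went from 1.77 to 3.36 in WT and from 1.83 to 4.17 in Ccr2KO cells between untreated and day 40, and the pan-leukocyte mean was 4.04 and 3.60 at day 28.

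At day 28 alone the neutrophil granule genes Ngp (4.42 ± 0.14, adjusted p = 0.00809) and Mpo (4.01 ± 0.20), Spp1 (4.50 ± 0.21) and Ptprc (1.38 ± 0.19, adjusted p = 0.0207) rose, and the haemoglobin gene Hba-a1 (−3.47 ± 0.35) and Ager (−1.46 ± 0.29, adjusted p = 0.043) fell. At day 40 Ngp (2.08 ± 0.14), Mpo (2.60 ± 0.20), Spp1 (3.61 ± 0.21) and Acta2 (1.31 ± 0.21, adjusted p = 0.0302) rose and Ptprc fell by 1.16 ± 0.19 (adjusted p = 0.0303), while Hba-a1 (−1.34 ± 0.35, adjusted p = 0.0775) and Ager (−1.40 ± 0.29, adjusted p = 0.0502) did not pass. Acta2 at day 28 gave 0.64 ± 0.21 (adjusted p = 0.112). Grem1 (7.86 ± 0.55 and 8.52 ± 0.55), Timp1 (3.34 ± 0.16 and 3.37 ± 0.16), Cxcl5 (4.53 ± 0.19 and 4.97 ± 0.19) and Col1a1 (1.47 ± 0.18 and 1.70 ± 0.18) rose at both times. In all 2827 genes changed at day 28 (1510 up, 1317 down) and 2506 at day 40 (1400 up, 1106 down), n = 2 arrays against 2. The day 28 count was 0 without either day 28 array and 1534 without Ccr2KO untreated. The day 40 count was 0 without WT day 28, Ccr2KO day 28 or Ccr2KO day 40, 552 without WT day 40, 1590 without WT untreated and 1602 without Ccr2KO untreated, and both counts were 0 with the slide row as a block.

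Between day 28 and day 40, leukocyte genes fell together. The largest decreases by the naming rule were in Htr7, a serotonin receptor gene (at least 12.8-fold), the B cell genes Fcrl1 (−3.58 ± 0.42), Ms4a1, encoding CD20 (−3.33 ± 0.34, adjusted p = 0.0262), Bank1 (−3.31 ± 0.26) and Fcmr, an IgM receptor gene (−3.26 ± 0.37). Gpr141 (−3.50 ± 0.24) and Slfn4 (−3.27 ± 0.37) also fell. Mmp25, a neutrophil metalloproteinase gene, fell at least 11-fold, Zfp831 at least 10.8-fold, Kynu, encoding kynureninase, at least 10.7-fold and Slfn1 at least 10.4-fold, none well above background at day 40 (a second Kynu probe gave −2.66). The largest increases came mostly from genes not well above background at day 28: the olfactory receptor gene Olfr32 (at least 49.6-fold), the formyl peptide receptor relative Fpr-rs4 (30.7), Cyp24a1, a vitamin D hydroxylase gene (18.4), Gsc2 (12.5), Hamp, encoding hepcidin (11.9), Zfp42 (9.78), Rbm20, a splicing factor gene (9.29), Hsd17b1 (8.94), Ifi202b (8.48), Olah (4.94) and Wfdc15b (4.22). Apold1, an endothelial early response gene, was detected on all arrays and rose by 1.90 ± 0.12 (adjusted p = 0.0147). Ptprc fell by 2.54 ± 0.18 (adjusted p = 0.0157). Of the other genes chosen in advance none passed: Spp1 −0.89 ± 0.21, Ccl12 −1.36 ± 0.24, Ccr2 −2.61 ± 0.81, Ccl2 0.32 ± 0.26, Ccl7 0.66 ± 0.39, Ccl8 0.63 ± 0.71, Acta2 0.67 ± 0.21, Col1a1 0.23 ± 0.18, Col3a1 0.04 ± 0.19, Fn1 0.24 ± 0.13, Timp1 0.03 ± 0.16, Pecam1 0.43 ± 0.20, Sftpc 0.31 ± 0.11, Scgb1a1 0.31 ± 0.11 and Ager 0.06 ± 0.29 (adjusted p from 0.0925 to 0.936). In all 448 of 16440 genes differed, 33 up and 415 down (n = 2 arrays against 2), with 2658 at an unadjusted p below 0.05.

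The list test for day 40 minus day 28 was chosen after seeing the data and called 10 of 53 lists up and 9 down. Of 12 pan-leukocyte genes 11 fell (median −2.44, camera adjusted p = 4.68e-20), and of 10 B cell genes 7 fell (−2.79, adjusted p = 1.93e-15). Of 13 T and NK cell genes 7 fell, among them Cd2 (−2.32 ± 0.11) and Cd3g (−2.30 ± 0.12) (−1.91, adjusted p = 1.93e-15), and of 11 neutrophil genes 6 fell, among them Cxcr2 (−3.21 ± 0.20) and S100a8 (−2.68 ± 0.13) (−2.13, adjusted p = 9.22e-12). In these 4 lists 1, 3, 6 and 5 genes did not pass, and 12, 10, 11 and 8 fell when adjusted over the list alone. MHC class II presentation (3 of 10 fell, H2-Ob −2.59 ± 0.19, H2-Oa −2.04 ± 0.13 and H2-DMb2 −1.56 ± 0.20, median −0.63, adjusted p = 2.76e-10), macrophages and monocytes (1 of 16 fell, Csf1r −1.71 ± 0.20, median −1.66, adjusted p = 4.67e-10), plasma cells (3 of 10 fell, among them Irf4 −2.61 ± 0.34 and Pou2af1 −2.40 ± 0.29, median −1.17, adjusted p = 0.000144) and inflammatory chemokines and cytokines (4 of 26 fell, Il1b −2.71 ± 0.11, Ccl17 −2.46 ± 0.15, Cxcl2 −1.96 ± 0.16 and Cxcl3 −1.67 ± 0.21, median −0.08, adjusted p = 0.0058) had 7, 15, 7 and 22 members that did not pass, and 7, 10, 5 and 7 that fell when adjusted over the list alone. The cell cycle median was −0.32 (adjusted p = 1.98e-09) with none of 29 genes passing, and 0 when adjusted over the list alone. Each of these 9 lists had adjusted p = 0.597 with an estimated correlation.

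Lists shifted up at day 40 were mostly shifts of many small values. No member passed over all genes for immediate early genes (median 0.62, camera adjusted p = 8.75e-08, 15 of 21 up when adjusted over the list alone; adjusted p = 0.665 with an estimated correlation), endothelial cells (0.48, adjusted p = 0.000159, 0 of 16 when adjusted over the list alone; adjusted p = 0.665 with an estimated correlation) or erythroid cells (2.13, adjusted p = 0.000187, 6 of 9 when adjusted over the list alone; adjusted p = 0.665 with an estimated correlation). The same held for the interferon-gamma response (0.45, adjusted p = 0.000393, 5 of 22 when adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), mucous cells (0.32, adjusted p = 0.0156, 0 of 12 when adjusted over the list alone; adjusted p = 0.597 with an estimated correlation) and TGF-beta targets (0.42, adjusted p = 0.0236, 5 of 15 up and 1 down when adjusted over the list alone; adjusted p = 0.597 with an estimated correlation). It also held for club cells (0.35, adjusted p = 0.0325, 0 of 10 when adjusted over the list alone; adjusted p = 0.683 with an estimated correlation) and heat shock proteins (0.36, adjusted p = 0.0464, 0 of 12 when adjusted over the list alone; adjusted p = 0.824 with an estimated correlation). The cartilage matrix gene Comp rose by 1.16 ± 0.15 (adjusted p = 0.045) among 25 matrix glycoproteins, 24 of which did not pass (median 0.32, adjusted p = 0.0156; adjusted p = 0.597 with an estimated correlation), 2 when adjusted over the list alone. The fibroblast gene Cthrc1 rose by 1.05 ± 0.14 (adjusted p = 0.0481) among 14 activated fibroblast genes, 13 of which did not pass (median 0.43, adjusted p = 0.0236; adjusted p = 0.665 with an estimated correlation), 3 when adjusted over the list alone. Fry called 8 lists, 6 of them called by camera, and 0 were called with an estimated correlation. The 448 genes fell to 0 when any of the 4 silica arrays was left out and with the slide row as a block, and rose to 689 without either untreated array. Within slide row 2, which held both WT silica arrays, the pan-leukocyte median was −2.35.

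Between genotypes, 0 of 16440 genes passed (limma, smallest adjusted p = 0.254). The largest positive values were in the stefins Stfa1 (2.89 ± 0.45), Stfa3 (2.53 ± 0.29) and Cstdc5 (1.97 ± 0.19), Prg2, encoding eosinophil major basic protein (2.70 ± 0.36), the neutrophil granule genes Ngp (2.52 ± 0.11) and Mpo (2.08 ± 0.16), and the chemokines Cxcl9 (2.35 ± 0.54) and Ccl8 (1.99 ± 0.58). The largest negative values were in Ccr2, Kif12 (−2.63 ± 0.73), Serpinb10 (−2.61 ± 0.20), Gpr141 (−2.59 ± 0.20), the monocyte marker F13a1 (−2.54 ± 0.32) and the glutamate receptor gene Gria1 (−2.52 ± 0.96). Gria1 was well above background on neither Ccr2KO silica array, so its size is not exact. The olfactory and vomeronasal receptor genes Olfr173 and Vmn1r82 were at least 8.72- and 6.28-fold lower. Adjusted p of these 16 genes lay between 0.254 and 0.547, with the same sign on all 3 days. Among the genes chosen in advance, none passed: Ccl7 1.35 ± 0.32, Ccl2 1.34 ± 0.21, Spp1 0.76 ± 0.17, Ccl12 0.67 ± 0.19, Timp1 0.49 ± 0.13, Fn1 0.38 ± 0.11, Acta2 0.37 ± 0.17, Col1a1 0.18 ± 0.15, Col3a1 0.16 ± 0.15, Sftpc 0.14 ± 0.09, Scgb1a1 0.14 ± 0.09, Ager −0.01 ± 0.24, Pecam1 −0.16 ± 0.16 and Ptprc −0.82 ± 0.15 (adjusted p from 0.381 to 0.99). An unadjusted p below 0.05 was reached by 1526 genes, 865 higher and 661 lower in Ccr2KO cells. With normexp background correction 1 gene passed (Prg2 1.96 ± 0.09, adjusted p = 0.0135), and Ngp passed with the authors' table (2.29 ± 0.12, adjusted p = 0.0323), with probes above background on all 6 arrays (2.52 ± 0.11, adjusted p = 0.0409) and with an intensity trend (2.52 ± 0.13, adjusted p = 0.0243).

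Of the 53 lists, camera called 15 higher and 10 lower in Ccr2KO cells, 0 with an estimated correlation (smallest adjusted p = 0.568) and 0 with fry (smallest adjusted p = 0.106), and no member of any list passed over all genes. Pan-leukocyte genes were lower (12 not passing, median −0.65, camera adjusted p = 3.79e-11, 9 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Fcer1g (−0.87 ± 0.24), Cytip (−0.86 ± 0.11), Coro1a (−0.84 ± 0.15) and Tyrobp (−0.83 ± 0.26) were members. Beside this leukocyte shift, activated fibroblast genes were higher (14 not passing, median 0.55, camera adjusted p = 4.13e-06, 4 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Grem1 (1.33 ± 0.45), Tnc (1.06 ± 0.23) and Col8a1 (0.95 ± 0.12) were members. Fibrillar and network collagens were higher (18 not passing, median 0.37, camera adjusted p = 1.1e-05, 2 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Col5a3 (0.49 ± 0.24) was part of it. Matrix proteases and inhibitors were higher (19 not passing, median 0.42, camera adjusted p = 6.9e-05, 1 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Mmp13 (1.81 ± 0.42), Ctsk (1.07 ± 0.36), Adamts4 (0.98 ± 0.51) and Mmp14 (0.82 ± 0.09) were in this list. Matrix glycoproteins and crosslinking genes were higher (25 not passing, median 0.28, camera adjusted p = 8.73e-05, 1 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Thbs2 (1.14 ± 0.23), Fmod (0.80 ± 0.09) and Lox (0.54 ± 0.20) were among its genes. Alveolar niche growth factors were higher (18 not passing, median 0.11, camera adjusted p = 0.0184, 4 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Rspo3 (1 ± 0.12), Pdgfc (0.99 ± 0.20), Igf1 (0.76 ± 0.22) and Nrg1 (0.72 ± 0.12) were among the genes of this list. The collagen median was 0.14 at day 0 within slide row 1, 0.59 at day 40 within slide row 2 and 0.35 with the row as a block, and that of activated fibroblasts 0.23, 0.72 and 0.64, while the pan-leukocyte median was −1, −0.42 and −0.78.

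Immune lists were split between the genotypes. Interferon-gamma response genes were higher (22 not passing, median 0.34, camera adjusted p = 7.47e-06, 0 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Cxcl9 (2.35 ± 0.54), Ubd (1.60 ± 0.83), Cxcl10 (1.15 ± 0.64) and Tgtp2 (0.48 ± 0.12) were members. Neutrophil genes were higher (11 not passing, median 0.57, camera adjusted p = 0.000207, 7 higher and 1 lower when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Ngp (2.52 ± 0.11), Mpo (2.08 ± 0.16), Camp (1.95 ± 0.32) and Stfa2 (1.43 ± 0.17) were members. Acute phase and innate defence genes were higher (19 not passing, median 0.28, camera adjusted p = 0.00457, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Saa3 (1.32 ± 0.51), Saa2 (1.07 ± 0.52), Saa1 (0.84 ± 0.20) and Serpina3n (0.64 ± 0.26) were members. CCR2 ligands and monocyte chemokines were higher (10 not passing, median 0.34, camera adjusted p = 0.0182, 5 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Ccl8 (1.99 ± 0.58), Ccl7 (1.35 ± 0.32), Ccl2 (1.34 ± 0.21) and Ccl12 (0.67 ± 0.19) were part of it. Mast cell and basophil genes were higher (7 not passing, median 1.14, camera adjusted p = 0.0134, 3 higher and 1 lower when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Cpa3 (1.49 ± 0.36), Fcer1a (1.26 ± 0.30), Mcpt4 (1.25 ± 0.79) and Cma1 (1.14 ± 0.58) were in this list. Complement genes were higher (17 not passing, median 0.34, camera adjusted p = 0.0182, 0 when adjusted over the list alone; adjusted p = 0.623 with an estimated correlation). C1qc (0.54 ± 0.26), C1qa (0.47 ± 0.27), C4b (0.46 ± 0.27) and C2 (0.44 ± 0.15) were among its genes. MHC class I presentation genes were higher (13 not passing, median 0.16, camera adjusted p = 0.0328, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). H2-T23 (0.25 ± 0.09), Tap1 (0.24 ± 0.10), H2-K1 (0.23 ± 0.11) and B2m (0.22 ± 0.10) were among the genes of this list.

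Lymphocyte lists lay the other way. B cell genes were lower (10 not passing, median −0.53, camera adjusted p = 8.73e-05, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Fcmr (−0.79 ± 0.31), Ms4a1 (−0.78 ± 0.27) and Fcrla (−0.67 ± 0.14) were among its members. MHC class II presentation genes were lower (10 not passing, median −0.24, camera adjusted p = 6.9e-05, 0 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). H2-Ob (−0.65 ± 0.15), H2-Oa (−0.42 ± 0.11), H2-Aa (−0.28 ± 0.09) and H2-DMa (−0.25 ± 0.09) belonged to this list. T and NK cell genes were lower (13 not passing, median −0.21, camera adjusted p = 0.0283, 0 when adjusted over the list alone; adjusted p = 0.666 with an estimated correlation). Klrb1c (−0.80 ± 0.34), Ncr1 (−0.70 ± 0.52), Gzma (−0.65 ± 0.28) and Cd2 (−0.41 ± 0.09) were members.

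Among lists of structural cells, AT2 genes were lower in Ccr2KO cells (14 not passing, median −0.22, camera adjusted p = 6.52e-05, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Lrp2 (−0.45 ± 0.15), Napsa (−0.43 ± 0.14), Slc34a2 (−0.35 ± 0.12) and Sfta2 (−0.31 ± 0.09) were part of it. Surfactant lipid genes were lower (15 not passing, median −0.16, camera adjusted p = 0.00335, 0 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Fabp5 (−0.30 ± 0.09) and Pla2g1b (−0.27 ± 0.10) were in this list. Endothelial genes were lower (16 not passing, median −0.17, camera adjusted p = 0.000775, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Tek (−0.51 ± 0.37), Sox17 (−0.41 ± 0.31), Ptprb (−0.36 ± 0.16) and Cldn5 (−0.29 ± 0.15) were among its genes. Alveolar capillary endothelium genes were lower (10 not passing, median −0.25, camera adjusted p = 0.012, 0 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Kit (−0.66 ± 0.42), Aplnr (−0.62 ± 0.63), Hilpda (−0.48 ± 0.16) and Gpihbp1 (−0.42 ± 0.17) were among the genes of this list. Cardiac and skeletal muscle genes were lower (12 not passing, median −0.22, camera adjusted p = 0.000736, 1 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Myh1 (at least 2.56-fold lower), Actc1 (−1.02 ± 0.31), Sln (−0.90 ± 0.20) and Myh6 (−0.90 ± 0.11) were members. Erythroid genes were lower (9 not passing, median −0.66, camera adjusted p = 0.00436, 0 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Epb42 (at least 2.13-fold lower), Hba-a1 (−0.70 ± 0.28), Hbb-bt (−0.70 ± 0.25) and Hbb-b2 (−0.67 ± 0.26) were members. Ciliated cell genes were higher (14 not passing, median 0.18, camera adjusted p = 0.00669, 0 when adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). Cfap126 (0.32 ± 0.09), Foxj1 (0.25 ± 0.11), Dnah5 (0.25 ± 0.09) and Tmem212 (0.24 ± 0.09) were members. Cell cycle genes were higher (29 not passing, median 0.18, camera adjusted p = 0.0172, 0 when adjusted over the list alone; adjusted p = 0.654 with an estimated correlation). Aurka (0.48 ± 0.20), Ccne1 (0.45 ± 0.11), Kif11 (0.44 ± 0.21) and Tpx2 (0.30 ± 0.20) were part of it. Senescence and p53 genes were higher (16 not passing, median 0.29, camera adjusted p = 0.043, 1 when adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). Cdkn2a (1.96 ± 0.16), Eda2r (1.18 ± 0.85), Gdf15 (0.51 ± 0.89) and Phlda3 (0.49 ± 0.39) were in this list.

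Leaving out either array of a day ended several genotype calls. Without a day 0 array these were cell cycle (0.13, adjusted p = 0.0723), complement (0.18, adjusted p = 0.23), growth factors (0.10, adjusted p = 0.0815), MHC class I (0.14, adjusted p = 0.0815), p53 (−0.05, adjusted p = 0.583) and T and NK cells (−0.11, adjusted p = 0.365). Without a day 28 array, and with the slide row as a block, they were CCR2 ligands (0.31, adjusted p = 0.0775), cell cycle (0.12, adjusted p = 0.535), ciliated cells (0.16, adjusted p = 0.164), mast cells (0.72, adjusted p = 0.187) and MHC class I (0.16, adjusted p = 0.286). Without a day 40 array they were alveolar capillary endothelium (−0.11, adjusted p = 0.0686), complement (0.27, adjusted p = 0.0743), endothelial cells (−0.04, adjusted p = 0.172), erythroid cells (−0.33, adjusted p = 0.0713) and T and NK cells (−0.16, adjusted p = 0.0513). Without a day term the calls of neutrophils (adjusted p = 0.277), mast cells (0.0695), acute phase (0.791), matrix glycoproteins (0.073) and 7 further lists ended. With silica as 1 group against day 0 those of B cells (adjusted p = 0.106), neutrophils (0.0952) and 4 further lists ended. The authors' table ended the alveolar capillary (−0.48, adjusted p = 0.17), erythroid (−0.86, adjusted p = 0.0825), MHC class I (−0.07, adjusted p = 0.159) and T and NK cell calls (−0.56, adjusted p = 0.0906). Normexp and quantile normalization ended those of p53 (adjusted p = 0.0666 and 0.0506) and MHC class I (0.104 and 0.231). Activated fibroblasts, collagens, AT2 cells and MHC class II stayed called under every alternative except the estimated correlation and fry. Matrix proteases, the interferon-gamma response, surfactant lipids, cardiac muscle and pan-leukocyte genes did so in the alternatives chosen before the data were examined, and lost the call with the leukocyte covariate. For pan-leukocyte genes this loss was built in, because the covariate is the mean of that list.

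Across 16440 genes the WT and Ccr2KO silica responses correlated with r = 0.742 (Spearman rho = 0.694), and 76.3% of genes had the same sign, although no array is shared between the 2 responses. Of 2014 genes with a response of at least 2-fold in WT, 92.3% had the same sign in Ccr2KO cells and 63.5% also passed 2-fold there, and of 2188 such genes in Ccr2KO cells 91.8% had the same sign in WT. In 20 simulations of independent genes without any effect at most 28 (median 19.5) changed at least 2-fold in all 4 silica arrays. The correlation was at most 0.114 in size. Neither is a benchmark for genes that vary together.

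**Figure D3:**
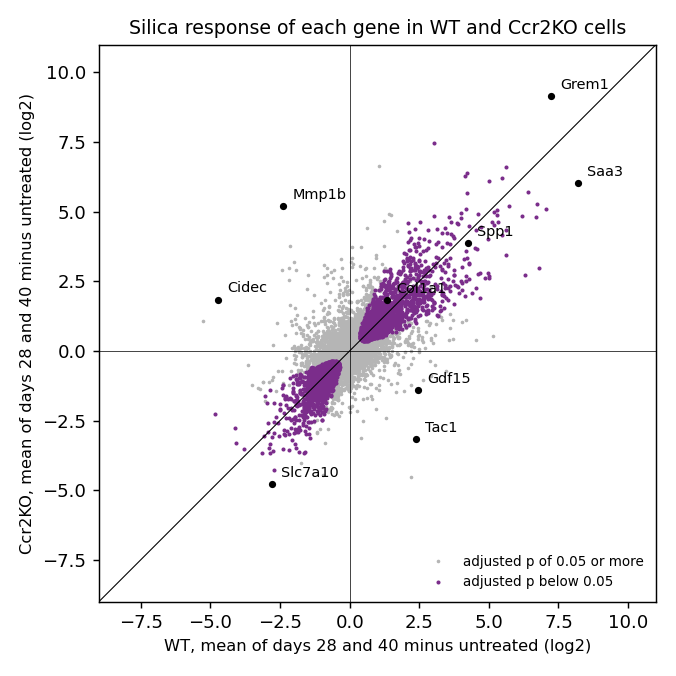
Silica response of 16440 genes in WT (horizontal axis) and Ccr2KO cells (vertical axis), each as the mean log2 signal of days 28 and 40 minus untreated, with genes passing an adjusted p of 0.05 for silica in purple and the others in grey. The responses correlated with r = 0.742, and labelled genes include Mmp1b and Cidec, positive in Ccr2KO and negative in WT cells, and Gdf15 and Tac1, positive in WT and negative in Ccr2KO cells.

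For the genotype by silica term 0 of 16440 genes passed (limma, smallest adjusted p = 1), with 618 at an unadjusted p below 0.05. A positive value is a Ccr2KO response above the WT response, whatever the direction of each. Among the genes of the naming rule, the fatty acid binding protein gene Fabp1 (6.33 ± 1.54) and the macrophage scavenger receptor gene Marco (5.33 ± 1.04) had positive values. Clca1 (−4.62 ± 0.46), the stress cytokine gene Gdf15 (−3.86 ± 0.40) and Ccdc184 (−3.68 ± 0.23) had negative ones, and none of these passed. The other genes of the rule are given without a size here, because 1 or both untreated arrays, or both Ccr2KO silica arrays for Gria1, were not well above background. Of these Mmp1b, a collagenase gene, the lipid droplet gene Cidec, the mast cell protease gene Mcpt2 and Trim29 were positive. Tac1, encoding substance P, Csf3, Ubd and Gria1 were negative. Col11a1, Fcnb and Kcna10 were well above background on neither untreated array, so no direction is read. Genes chosen in advance gave Ccr2 2.74 ± 2.34, Ccl8 2.10 ± 0.90, Acta2 0.55 ± 0.65, Col1a1 0.48 ± 0.31, Col3a1 0.41 ± 0.28, Ptprc 0.40 ± 2.25, Scgb1a1 −0.03 ± 0.34, Sftpc −0.14 ± 0.35, Timp1 −0.19 ± 0.29, Pecam1 −0.21 ± 0.52, Fn1 −0.23 ± 0.31, Spp1 −0.37 ± 0.86, Ccl2 −0.70 ± 0.43, Ccl12 −0.73 ± 1.22, Ager −0.86 ± 0.32 and Ccl7 −1.27 ± 0.66. Ccr2KO against WT among silica arrays likewise gave 0 genes (smallest adjusted p = 1), with 622 at an unadjusted p below 0.05. On simulated data this term recovered 0% of 2-fold and 0% of 8-fold differences, so the count of 0 leaves even 8-fold differences open.

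For the genotype by silica term camera called 5 lists up and 10 down. None was called with fry (smallest adjusted p = 0.995) or an estimated correlation (each adjusted p = 0.986), and no member passed over all genes. Mast cell and basophil genes were higher (7 not passing, median 1.11, camera adjusted p = 8.51e-05, 0 when adjusted over the list alone). Mcpt4 (3.42 ± 0.87), Cma1 (2.49 ± 0.70), Cpa3 (1.49 ± 0.53) and Fcer1a (1.11 ± 0.42) were among its genes. Fibrillar and network collagens were higher (18 not passing, median 0.38, camera adjusted p = 9.59e-05, 1 when adjusted over the list alone). Col15a1 (1.04 ± 0.87) and Col5a3 (0.84 ± 0.33) were members. Sterol synthesis genes were higher (20 not passing, median 0.27, camera adjusted p = 0.000961, 0 when adjusted over the list alone). Stard4 (0.56 ± 0.35), Sqle (0.47 ± 0.26) and Dhcr7 (0.45 ± 0.32) were members. Macrophage and monocyte genes were higher (16 not passing, median 0.76, camera adjusted p = 0.0139, 1 when adjusted over the list alone). Marco (5.33 ± 1.04), Chil3 (3.30 ± 2.08), Ear2 (3.02 ± 1.89) and Mrc1 (2.32 ± 0.25) belonged to this list. Basal cell genes were higher (7 not passing, median 1.26, camera adjusted p = 0.0217, 0 when adjusted over the list alone). Krt5 (2.14 ± 1.1), Dapl1 (1.43 ± 0.74), Krt14 (1.40 ± 1.1) and Krt15 (1.26 ± 0.94) were members. The pan-leukocyte value for this term was 0.43 (camera adjusted p = 0.435), and −0.80 with the slide row as a block. The value with the block compares Ccr2KO day 40 with both WT silica days and cannot separate slide row from day.

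The 10 lists called down for this term had a Ccr2KO response below the WT response. Each had a higher mean in untreated Ccr2KO than in untreated WT cells. Senescence and p53 genes were lower (16 not passing, median −0.81, camera adjusted p = 1.82e-07, 7 when adjusted over the list alone). Gdf15 (−3.86 ± 0.40), Cdkn1a (−2.03 ± 0.23) and Phlda3 (−1.64 ± 0.23) were part of it. Heat shock genes were lower (12 not passing, median −0.77, camera adjusted p = 9.59e-05, 0 when adjusted over the list alone). Hspa1a (−3.41 ± 2.88), Hsph1 (−1.67 ± 0.48), Dnajb1 (−1.59 ± 0.91) and Dnaja1 (−1.31 ± 0.38) were in this list. Type I interferon response genes were lower (22 not passing, median −0.42, camera adjusted p = 2.51e-06, 0 when adjusted over the list alone). Oas2 (−1.53 ± 0.59), Ifit1 (−1.08 ± 0.25), Isg15 (−1.05 ± 0.22) and Oas1a (−0.97 ± 0.24) were among its genes. AT1 genes were lower (11 not passing, median −0.55, camera adjusted p = 3.17e-06, 0 when adjusted over the list alone). Igfbp2 (−2.08 ± 0.37), Spock2 (−1.40 ± 0.80), Hopx (−0.93 ± 0.38) and Emp2 (−0.88 ± 0.35) were members. Fibroblast genes were lower (17 not passing, median −0.54, camera adjusted p = 0.00157, 0 when adjusted over the list alone). Tcf21 (−1.63 ± 0.25), Inmt (−1.29 ± 0.66), Col13a1 (−1.23 ± 0.27) and Npnt (−1.06 ± 0.55) were members.

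Stress and defence lists were lower too. After silica the Ccr2KO mean was above WT on both days for acute phase and lymphoid stroma, and below for ER stress and immediate early genes. Acute phase and innate defence genes were lower (19 not passing, median −0.35, camera adjusted p = 0.00221, 3 when adjusted over the list alone). Saa3 (−2.18 ± 0.42) and Lcn2 (−1.08 ± 0.40) belonged to this list. NRF2 response genes were lower (18 not passing, median −0.38, camera adjusted p = 0.00585, 0 when adjusted over the list alone). Mt2 (−1.16 ± 0.77), Mt1 (−1.08 ± 0.72), Gsta3 (−0.92 ± 0.31) and Gsta2 (−0.88 ± 0.39) were members. Lymphoid stroma genes were lower (14 not passing, median −0.56, camera adjusted p = 0.00749, 0 when adjusted over the list alone). Tnfsf13b (−1.17 ± 0.29) and Cxcl13 (−0.88 ± 0.38) were part of it. ER stress genes were lower (18 not passing, median −0.36, camera adjusted p = 0.0108, 0 when adjusted over the list alone). Atf3 (−0.96 ± 1.03), Ddit3 (−0.88 ± 0.34), Hspa5 (−0.69 ± 0.33) and Dnajb9 (−0.56 ± 0.24) were in this list. Immediate early genes were lower (21 not passing, median −0.42, camera adjusted p = 0.0139, 0 when adjusted over the list alone). Myc (−1.23 ± 0.42), Fosb (−1.01 ± 0.76), Atf3 (−0.96 ± 1.03) and Zfp36 (−0.87 ± 0.90) were among its genes. Without Ccr2KO day 28, and with the slide row as a block, the macrophage (0.22, adjusted p = 0.474) and immediate early (−0.07, adjusted p = 0.371) calls ended. The block also added 8 calls: cell cycle (−0.40), adipocytes (1.14), activated fibroblasts (0.54), inflammatory chemokines (−0.52), club cells (0.49), B cells (−1.91), complement (−0.29) and MHC class II (−0.52). Both WT silica arrays lie in one slide row, so the row term takes up Ccr2KO day 40 minus day 28. The block thus equals leaving out Ccr2KO day 28 and cannot separate slide row from day. Without WT day 28 the basal cell (0.84, adjusted p = 0.0526) and NRF2 (−0.35, adjusted p = 0.0676) calls ended, and without WT day 40 the macrophage (−0.16, adjusted p = 0.902), immediate early (−0.11, adjusted p = 0.346) and ER stress (−0.24, adjusted p = 0.0783) calls ended. Quantile normalization ended the calls of ER stress (−0.30, adjusted p = 0.0517) and immediate early genes (−0.32, adjusted p = 0.0572). Probes above background on all 6 arrays ended that of acute phase genes (−0.22, adjusted p = 0.0742).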

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

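Of the tests given below, those of the slide row for the day 40 decrease, of a lower leukocyte share for the matrix lists, and both for the p53 and heat shock lists were chosen only after the result was seen, as was the 2-fold count of unnamed probes.

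Camera called a genotype difference in the silica response for 15 lists: p53 and senescence (−0.81), heat shock proteins (−0.77), lymphoid organ stroma (−0.56), AT1 cells (−0.55), fibroblasts (−0.54), immediate early genes (−0.42), type I interferon response (−0.42), NRF2 (−0.38), ER stress (−0.36), acute phase (−0.35), sterol synthesis (0.27), collagens (0.38), macrophages (0.76), mast cells (1.11) and basal cells (1.26). None was called with an estimated correlation or fry.

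For 8 named genes both silica arrays of a genotype moved one way and both of the other genotype the opposite way, and the difference was not tested beyond the gene fit, in which none passed. They were Mmp1b (7.58; WT −3.02 to −1.75, Ccr2KO 3.65 to 6.75), Cidec (6.57; −6.26 to −3.20, 1.08 to 2.60), Fabp1 (6.33; −6.48 to −4.04, 0.99 to 1.15), Marco (5.33; −3.20 to −1.66, 2.64 to 3.17), Trim29 (4.22; −1.87 to −1.10, 2.61 to 2.86), Ccdc184 (−3.68; 2.64 in both WT arrays, −1.10 to −0.97), Gdf15 (−3.86; 2.38 to 2.53, −1.66 to −1.14) and Tac1 (−5.52; 1.71 to 3.02, −3.90 to −2.42). Each pair of values shares 1 untreated array. For Mmp1b, Cidec, Trim29 and Tac1 1 of the 2 untreated arrays was below background, so only the directions are read and the sizes are not exact. Over all genes 1438 of 16440 had such opposite directions.

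Signal in probes without a gene symbol was also seen. Of 14881 such probes, limma called 0 after silica (smallest adjusted p = 0.056, 3597 at an unadjusted p below 0.05). At least 2-fold changes in all 4 silica arrays were found in 135 up and 217 down.

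Of the 415 genes lower at day 40 than at day 28, 377 lay outside the leukocyte lists. The slide row is argued against, since in the WT pair, both in one slide row, the pan-leukocyte median was −2.35 with 12 of 12 genes lower (Ccr2KO pair −2.41), while the slide column differed in that pair and was not tested. RNA of leukocytes left in the preparations could account for it: these 377 genes were also lower in untreated Ccr2KO than in untreated WT cells, by a median of −0.51 (315 of 377 lower, interquartile range −0.91 to −0.14), where the pan-leukocyte median was −1. A difference between the 2 times after silica in the leukocytes of the lung stays open and was not tested.

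The collagen and activated fibroblast lists were higher in Ccr2KO cells (31 genes, median 0.43). A lower leukocyte share as the whole cause is argued against, since it would raise other CD45-negative types alike, while endothelial and AT2 genes had a median of −0.18 (28 of 30 lower, interquartile range −0.30 to −0.11). The slide row is argued against too, with 0.44 when the row was a block, and the slide column was not tested. For Ccr2KO against WT the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05: the real split gave 0 genes (highest other 0, so 10 of 10 splits were as large), 1526 at an unadjusted p below 0.05 (highest other 1368, 1 split as large) and 25 lists (highest other 21, 1 split as large). Day was kept as a term, so a split with both arrays of a day on one side rested on WT against Ccr2KO of 1 day. The highest other values came from such splits, so they hold the genotype difference and do not measure chance. Splits that swapped the genotypes within a day gave 370, 521 and 817 genes at an unadjusted p below 0.05. They gave 10, 15 and 20 lists. A genotype effect and a difference between single pools both stay open.

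The p53 and heat shock lists had a negative genotype by silica term. The difference lay in the untreated pair: the 28 genes had a median Ccr2KO minus WT difference of 0.69 at day 0 and −0.10 at days 28 and 40, so 1 untreated array may decide it. Handling stress in the untreated Ccr2KO preparation is a possible explanation, since immediate early genes were higher there by 0.37 (19 of 21 higher) and by −0.06 later, although that list was itself among the 15 above. A low untreated WT array stays open too: its p53 list mean was 1.41 against 2.16 to 2.45 on the other 5 arrays, but its median was 2.13 against 2.11 to 2.61. The heat shock mean was 4.44 there, 5.30 in untreated Ccr2KO and 4.42 to 5.27 after silica. A genotype difference in untreated cells was not tested.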

How the results depend on the processing

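The leukocyte covariate was chosen only after the result was seen. Of 2703 comparisons of a list under an alternative, 2304 kept direction and side of the threshold, 253 no longer passed, 125 newly passed and 21 reversed, and of 6051 for named genes 5194, 800, 56 and 1 did so. No scaling or background alternative reversed a list or named gene. For all values below the cause was not tested, unless stated. With an estimated correlation 0 lists were called after silica, 0 for Ccr2KO minus WT and 0 for genotype by silica, and fry called 0 in the last 2. Normexp background correction, run on the median spot signal in place of the mean named beforehand, gave 702 genes for day 40 against day 28 (145 up, 557 down), 1 for Ccr2KO against WT, 478 genes at least 2-fold changed in all 4 silica arrays, and a Ccr2 difference of −2.43. The authors' table gave 4937 genes after silica (1309 up, 3628 down), 6117 at day 40 (938 up, 5179 down), 883 for day 40 against day 28 and 1 for Ccr2KO against WT. It is not scaled between arrays, and the median of all genes shifted by −0.19, −0.34, −0.25 and −0.20. Without a filter the counts were 1877 after silica, 1422 at day 28, 1236 at day 40 and 233 for day 40 against day 28, and the agreement of the responses was r = 0.637. Probes above background on all 6 arrays gave 1 gene for Ccr2KO against WT, and the intensity trend 674 for day 40 against day 28 and 1 for Ccr2KO against WT. The slide row as a block left 1 residual degree of freedom and called 0 genes after silica, 0 at day 28, 0 at day 40 and 0 between them, with 2474, 3401, 1828 and 1639 at an unadjusted p below 0.05, and reversed the direction of camera for the B cells list (product), at a median of −1.91 that was negative before as well (−0.39). As above, this B cell value cannot separate slide row from day. Silica against day 0 without separate days gave 2032 genes, and no day term 14 lists for Ccr2KO minus WT. The leukocyte covariate, also with 1 residual degree of freedom, gave 604 genes after silica and 0 at day 28, 0 at day 40 and 0 between them. It reversed the direction of camera, after silica, for the immediate early (−0.04), macrophage (−0.29) and pan-leukocyte (−0.11) lists, and for Ccr2KO minus WT acute phase (−0.28), complement (−0.20), immediate early (−0.42), ER stress (−0.34), heat shock (−0.79), macrophages (0.79), NRF2 (−0.35), p53 (−0.84), sterol synthesis (0.31), T and NK cells (0.32) and type I interferon (−0.36). The medians of immediate early genes after silica (−0.22 before) and of macrophages (0.01) and sterol synthesis (0.02) for Ccr2KO minus WT kept their sign. The pan-leukocyte result was built in. Ccr2 itself then gave −0.07. Leaving out 1 array gave 0 to 1959 genes after silica (0 without WT day 28 or Ccr2KO day 28, 1499 without Ccr2KO day 40, 1612 without Ccr2KO day 0, 1909 without WT day 0), 0 to 2062 at day 28, 0 to 1602 at day 40 and 0 to 689 between them. A lone array was then assumed to vary like the others, and 1 residual degree of freedom was left. It moved heat shock proteins after silica between −0.56 (without WT day 0) and 0.32, heat shock proteins for Ccr2KO minus WT between −0.11 (without a day 0 array) and 0.26, p53 and senescence between −0.05 and 0.48, and B cells for genotype by silica between −1.91 (without Ccr2KO day 28) and 1.19. The genotype by silica comparison has no value without a day 0 array. No paired analysis was possible, with 1 array per group and no shared replicate numbers. Genes not well above background on the lower side have only nominal bounds.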

Other observations

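The tests of gene families and of genes next to Ccr2 were written before the results were seen, and the named genes chosen after.

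Interleukin genes and their receptors rose after silica more often than other genes (20 of 59, Fisher's exact test, adjusted p = 8.36e-05), among them Il4i1, an amino acid oxidase gene (4.13 ± 0.24), the IL-1 antagonist gene Il1rn (3.52 ± 0.28), Il17a (2.69 ± 0.12), Il1f9 (2.52 ± 0.20), Il2ra (2.09 ± 0.14), the IL-33 receptor gene Il1rl1 (1.90 ± 0.26) and Il13 (0.66 ± 0.10), while Il12a (−1.90 ± 0.23) and Il22ra2 (−1.45 ± 0.20) fell. Of 18 Tnfrsf genes 8 rose (adjusted p = 0.0141), with Tnfrsf26 (2.13 ± 0.34), Tnfrsf23 (1.88 ± 0.16), the RANK ligand decoy Tnfrsf11b (1.44 ± 0.14), Tnfrsf18 (1.44 ± 0.10) and Tnfrsf4 (1.22 ± 0.14). Serpina genes rose (10 of 16, adjusted p = 8.36e-05), with the antitrypsin genes Serpina1e (2.96 ± 0.35), Serpina1a (2.90 ± 0.36) and Serpina1c (2.72 ± 0.28). Speer genes rose (6 of 10, adjusted p = 0.0141), with Speer4a at 2.38 ± 0.45. Myosin heavy chain genes fell (6 of 9, adjusted p = 0.0065), with Myh7 (−2.29 ± 0.17), Myh7b (−1.94 ± 0.20), Myh8 (−1.91 ± 0.20) and Myh3 (−1.89 ± 0.18), while Myh9 rose (0.50 ± 0.10). These were the 5 of 268 families that passed in 536 tests.

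Passenger sequence of the donor strain left around the targeted gene was tested on the 23 nearest measured genes, 20 before and 3 after Ccr2. Their median absolute Ccr2KO minus WT difference was 0.16 against 0.12 elsewhere, at percentile 85.1 of 15972 windows of the same shape, and whether such sequence or local chance moved them cannot be told apart. The chemokine receptor genes beside it gave Ccr1 −1.05, Ccr3 −0.86 and Ccr9 −0.56, each lower on 3 of 3 days, beside the lower pan-leukocyte list.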
